A study of Mus musculus with 42 samples.

How the data were processed

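RNA of 21 v-abl-transformed mouse pre-B cell lines was hybridized to 42 Affymetrix arrays, 1 for each line untreated and 1 for each line 2 h after 1 Gy of gamma rays. The deposited values are probe-set intensities on a linear scale, made with MAS5 per the submitters' processing notes. Each array had a mean of 500 after trimming 2% at both ends. Labelling followed the one-cycle protocol of the manufacturer with biotin from total RNA, per the labels' protocols. Groups, treatments and replicate numbers were taken from the labels, which number the WT samples 1, 3 and 4 and those of each mutant 1, 2 and 3. The number of arrays, 3 per group, limits the precision.

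The table held 45101 probe sets, of which 64 were controls. Of the others, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were unnamed here; no gene was named from a probe set with several symbols. Of the Entrez identifiers of named probe sets, 34754 probe sets were found in the RefSeq table of assembly GRCm38.p6, which changed 0 symbols and was used here only for chromosomes and neighbouring genes. A probe set was kept if it lay above the median of its own array on at least 3 arrays, which left 28260 probe sets, 23245 of them with 1 symbol. For each gene the kept probe set with the highest mean was used, which gave 12363 genes, 5984 of them with more than 1 kept probe set; disagreements in sign are stated beside the gene. Genes may carry older symbols of the platform.

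Values were tested as log2(signal + 16), so that a change of a gene with a low signal is understated. In R 4.3.3, limma 3.58.1 fitted the mean of each of the 14 groups over all 42 arrays (28 residual degrees of freedom), with moderated variances that followed mean intensity. P-values were two-sided and Benjamini-Hochberg adjusted over genes within each comparison, with a threshold of 0.05; the 15 comparisons between pairs of mutants were adjusted jointly. Comparisons were the radiation response of each genotype, that of each mutant against WT, the differences among the 6 mutants (a moderated F test of 5 independent differences, and all pairs), and each untreated mutant against untreated WT. Shared calls were counted in the same direction, beside the overlap of independent lists. Radiation responses of different genotypes share no arrays, whereas comparisons with WT share the WT arrays. Values were read with the R package data.table (version 1.17.8), and the plots were drawn in Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.

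The 16 gene lists, the groups, the tests, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists and comparisons, and again with an estimated correlation. Unpaired, the estimate was 0.26 for p53, 0.102 for NF-kB, 0.32 for G2/M and 0.203 for G1/S genes. At the preset, p therefore treats these genes as more independent than estimated and overstates the evidence. Lists were also tested with fry, which asks whether a list's genes move 1 way on balance without comparing them with other genes. Of 112 list tests after radiation 31 were called, 21 up and 10 down, and 15 with an estimated correlation; wherever the estimate ended a call, its p stands beside the call. Genes of the list with targeted genes were reported for every genotype. Otherwise the named genes were the largest called changes whose irradiated and untreated arrays did not overlap (12 up and 8 down for WT, 5 up and 3 down per mutant), up to 10 genes per comparison with WT or F test, the 5 largest each way per untreated comparison, and up to 4 genes per list with the smallest p. Without any effect, 10% of genes would have arrays of 3 against 3 that do not overlap. The same rule was applied to the paired comparisons.

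Whether replicate numbers pair arrays was checked before the calls were compared. The deviations from group means correlated between 0.354 and 0.643 in all 21 pairs of arrays with the same genotype and number, and at most at -0.0526 between different numbers of a genotype. Xist and Eif2s3y, an X-linked transcript of females and a Y-linked gene, matched within all 21 pairs: 18 pairs had high Xist (at least 8935) and 3 had high Eif2s3y. Only Atm-/- and Mre11A/A lines, with 1 and 2 lines of the high-Eif2s3y kind, could have mismatched. In the other genotypes every line had high Xist and would match under any pairing. Both arrays of a number were therefore taken as 1 line, and each response was fitted again with the line as a block (14 residual degrees of freedom). Unpaired, differences in level between lines count as spread, which weakens the test of a response. Chance alone gives an unadjusted p under 0.05 for a share of 0.05 of the 12363 genes. Most unpaired counts of the responses lay below that share and so show no surplus. Untreated comparisons, where a line has 1 array per treatment, used the line as a random block with a correlation of 0.53.

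The fits were tested on simulated data with 200 changed genes among 12363. For the WT response, 32.8%, 58.2% and 77.3% of genes changed 1.5-, 2- and 4-fold were called unpaired, with 1 other gene called, and 49.3%, 71.6% and 89.4% paired, with 5 others. For the Scid response against WT the shares were 11.9%, 44.8% and 60.6% unpaired and 29.9%, 56.7% and 74.2% paired, and for untreated Mdc1-/- lines 25.4%, 56.7% and 81.8%. With no effect simulated, 0 genes were called by limma over the 7 responses.

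Alternatives were pseudocounts of 1 and 64, no filter and a filter at the 70th percentile, quantile normalization, centring on the 75th percentile, every kept probe set, no intensity trend, only the arrays compared, the line as a block, and each array or line left out in turn. After the data were examined, the comparison was also made without the irradiated arrays of WT line 4 and Atm line 2, whose signals were raised at the low end (5th percentile up to 8.51, against at most 5.16 on the others), and each alternative was repeated for the paired comparison. Correlations of log2 values ran from 0.961 to 0.985 within lines and from 0.916 to 0.972 between lines of a group, and no 2 arrays were identical. The ratio of 3' to 5' probe sets was 0.761 to 0.864 for Gapdh and 1.22 to 1.63 for Actb. Control probe sets were left out of all tests, and probe sets without a single symbol were counted separately. Scan dates were not used here.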

Results

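Gene expression was measured in 21 mouse pre-B cell lines of 7 genotypes, with 3 lines per genotype, on 42 Affymetrix arrays. The lines had been made by transforming bone marrow of Eμ-Bcl2 transgenic mice with a retrovirus carrying v-abl, an oncogenic tyrosine kinase; the Bcl2 transgene protects cells from apoptosis. Each line was sampled untreated and 2 h after 1 Gy of ionizing radiation, which gave 3 arrays per genotype and treatment. The genotypes were wild type (WT), Atm-/- (Atm is the kinase that starts signalling from DNA double-strand breaks), Scid (a mutation of Prkdc, the catalytic subunit of the end-joining kinase DNA-PK), Mre11A/A (a hypomorphic allele of the nuclease of the Mre11 complex, which binds broken ends), and 53bp1-/-, H2ax-/- and Mdc1-/- (proteins of the chromatin around a break). The study asked how each line responded to radiation, and how that response compared with that of WT lines and of the other mutant lines. The labels call the 3 arrays of a group biological replicates, and the arrays of the same number within a genotype were taken as the same line. Each comparison is given first with the arrays taken as independent ("unpaired") and then with both arrays of a line paired ("paired"), where pairing moved it. Log2 changes have standard errors (SE) from the unpaired limma fit, and signals are means ± SD of the deposited values. The SE rests on the spread within all groups and includes differences in level between lines. Beside a paired call it is therefore not the SE of the paired change.

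The targeted genes were looked at first, as a check of the labels. H2ax signal was 10750 ± 1590 over the 6 WT arrays and 69.5 ± 30.7 over the 6 H2ax-/- arrays (n = 6 each). Mdc1 signal was 418 ± 53.3 in WT and 60.8 ± 73.1 in Mdc1-/- lines. The Atm probe set with 762 ± 41.3 in WT read 184 ± 69.9 in Atm-/- lines, and the Mre11a signal was 1497 in WT and 559 ± 101 in Mre11A/A lines. A weaker Mre11a probe set was not lower in Mre11A/A lines, at 251 against 174. Trp53bp1, the gene of 53bp1, read 1480 ± 258 in WT and 978 ± 221 in 53bp1-/- lines, and its arrays overlapped between both genotypes (1176 to 1849 and 736 to 1291). Another of its probe sets read 733 ± 112 in WT (599 to 903) and 393 ± 84.2 in 53bp1-/- lines (295 to 505), without overlap. Prkdc signal was 593 ± 46.2 in WT and 525 ± 70.5 in Scid lines; the Scid allele is a point mutation, so the amount of this transcript checks nothing. Another Atm probe set, at 1518 in WT and 177 in Atm-/- lines, also read 320 ± 35.3 in H2ax-/- and 285 ± 9.45 in Mdc1-/- lines, where the first-named set read 841 and 785.

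**Figure D1:**
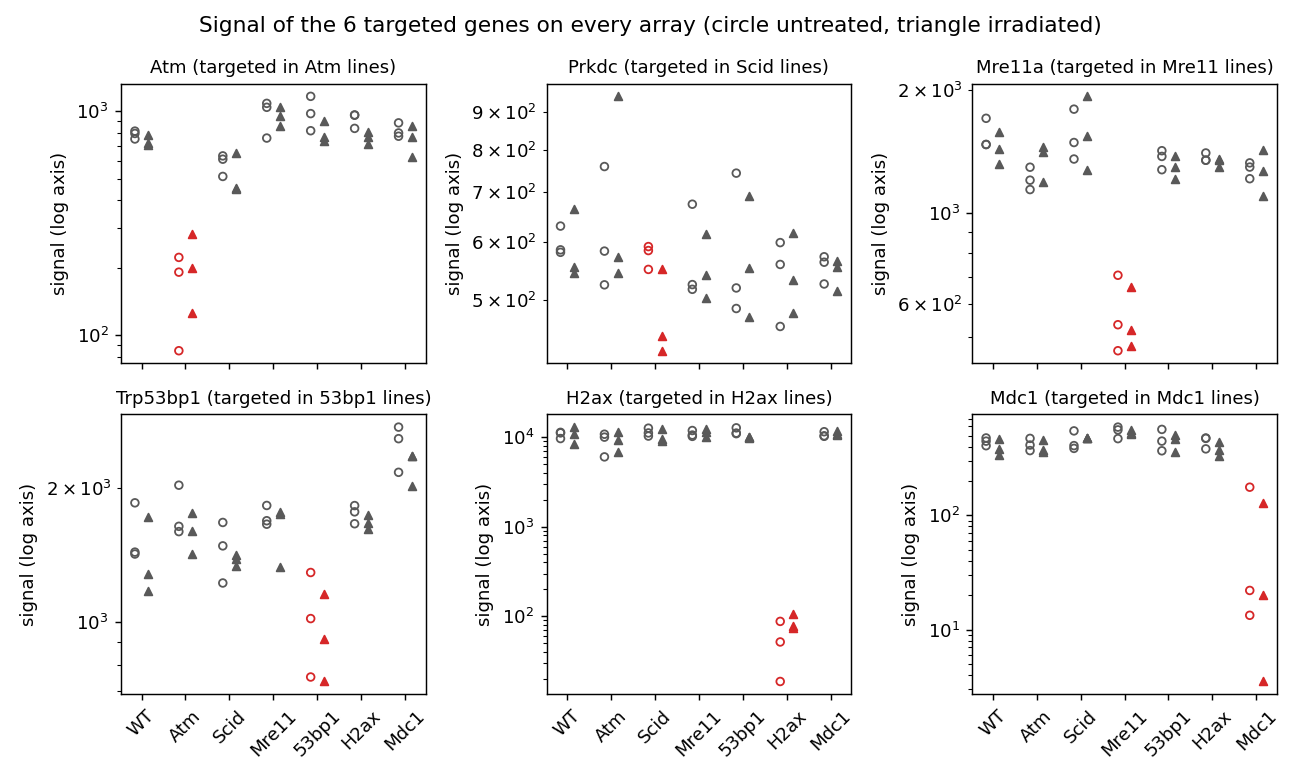
Signal of each targeted gene (log axis, deposited intensity) on every array, in 1 panel per gene, with genotypes along the horizontal axis, circles for untreated and triangles for irradiated arrays, and the gene's own genotype in red. H2ax, Mdc1, Atm and Mre11a signals lay lower in their own genotype (H2ax between 18.7 and 106.8), while the Trp53bp1 probe set shown overlapped with WT and Prkdc in Scid lines was close to WT.

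In WT lines, radiation raised a small set of NF-kB targets and immune receptors. Cd40, a TNF-receptor family member that drives NF-kB signalling in B cells, rose by a log2 change of 3.33 ± 0.44 (SE, n = 3 lines, adjusted p = 0.00016), from a signal of 49.4 ± 15.4 to 658 ± 220, and it was higher in 3 of 3 lines. Relb, an NF-kB subunit, rose by 2.91 ± 0.45, and Cd69, an early activation marker of lymphocytes, by 2.26 ± 0.35, from 1582 ± 489 to 7479 ± 1010 (adjusted p = 0.00079 for each). Nfkbie (2.32), Icam1 (1.56), Nfkb2 (1.41) and Birc3 (1.19, although another Birc3 probe set changed by 0.09), all NF-kB targets, rose as well. Pidd1, a p53 target (1.33), Swap70, a B-cell signalling protein (1.33), Mob3a (1.24) and Fchsd2 (1.22) completed the genes that rose. Dtl, which directs Cdt1 for degradation during DNA replication, was the single gene that fell, at -0.79 ± 0.15 (adjusted p = 0.02). In all, 12 of 12363 genes passed at an adjusted p under 0.05, 11 higher and 1 lower, and 615 had an unadjusted p under 0.05. The count was 5 without WT untreated replicate 1, 4 without WT irradiated replicate 3, 19 without Scid irradiated replicate 1 and 31 without H2ax irradiated replicate 2. Cd40, Cd69, Mob3a and Relb passed without each WT array in turn, and the other 8 did not.

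With both arrays of a line paired, 465 genes were called in WT lines (247 higher, 218 lower), with p53 targets and some cell-cycle genes among them. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, had a log2 change of 1.76 ± 0.81 (2761 to 8644, adjusted p = 0.94 unpaired and 8.1e-06 paired). It changed by 2.21, 1.8 and 1.28 in WT lines 1, 3 and 4. Paired calls were made for the p53 targets Bbc3 (1.43), Mdm2 (1.16), Sesn2 (1.58) and Polk (1.33), and for the stress gene Ddit4 (1.17), the B-cell transcription factors Spib (1.52) and Irf4 (0.70), Maff (1.91) and Ier3 (1.76). Among the genes lower in the paired comparison were Myc (-0.70, adjusted p = 0.0008), Cdc6 (-0.51) and Cdt1 (-0.29), which load replication origins, Rag1 (-1.15), the recombinase of antigen receptor genes, with its partner Rag2 (-0.85), and Casp9 (-0.81). The mitotic genes Kif2c (-0.43), Dlgap5 (-0.52), Aspm (-0.34) and Tpx2 (-0.26) were also lower. Without WT line 1 the paired count was 248 and without line 3 it was 114.

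**Figure D2:**
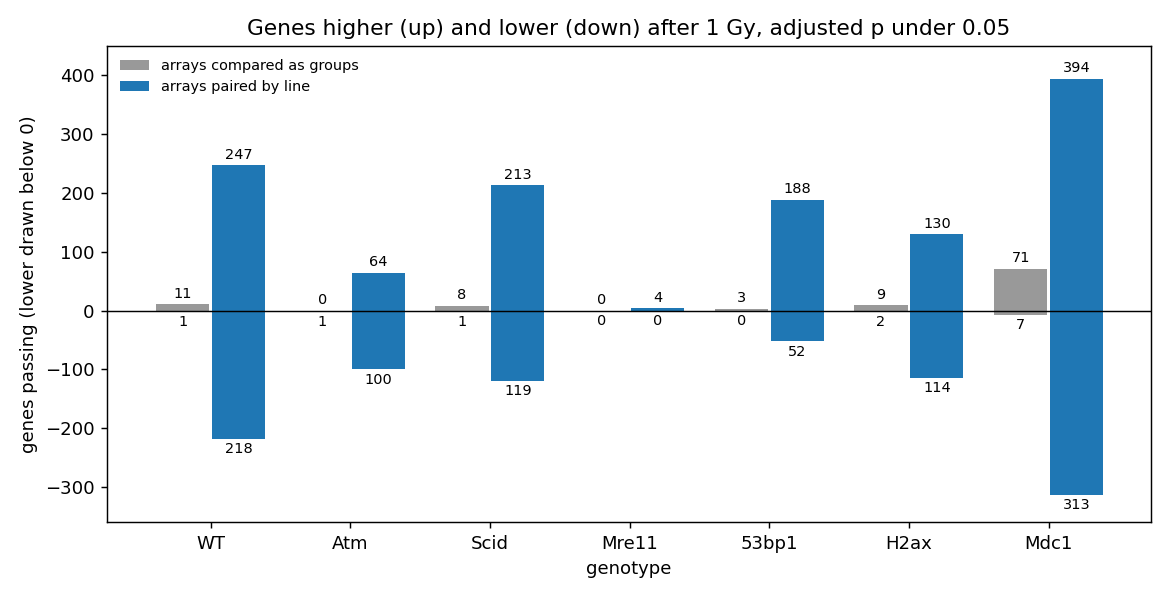
Number of genes higher and lower after radiation in each genotype (bars from 0; 3 lines each) at an adjusted p under 0.05, with grey bars for unpaired and blue bars for paired arrays. WT lines had 12 unpaired and 465 paired calls, Mre11A/A lines 0 and 4, and Mdc1-/- lines 78 and 707.

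Of the 16 gene lists, 5 were called in WT lines. The 34 measured p53 targets had a median log2 change of 0.81 (adjusted p = 2.86e-14, adjusted p = 0.0488 with an estimated correlation). Of these, 1 member, Pidd1, rose over all genes and 9 adjusted over the list alone. When paired, 20 rose over all genes, and 24 rose and 2 fell adjusted over the list alone. The 30 NF-kB targets had a median of 0.68 and a mean of 0.97 (adjusted p = 5.13e-23, adjusted p = 0.000109 with an estimated correlation). Among them 6 members rose over all genes and 11 adjusted over the list alone, or 16 and 19 when paired. The 32 G2/M and mitosis genes moved down by a median of -0.10 (adjusted p = 0.000713, adjusted p = 0.593 with an estimated correlation). When paired, 6 were lower, or 8 lower and 1 higher adjusted over the list alone. The 32 G1/S and replication genes also moved down, by -0.08 (adjusted p = 0.00568, adjusted p = 0.593 with an estimated correlation). The 20 lymphocyte homing genes moved up with a median of 0.06 and a mean of 0.43 (adjusted p = 0.000747, adjusted p = 0.0524 with an estimated correlation). Double-strand break repair (-0.05), immediate-early (0.08), heat shock (0.06) and apoptosis genes (0.12, paired adjusted p = 0.016, adjusted p = 0.259 with an estimated correlation) were not called unpaired. Medians for pre-B and B-cell genes (-0.02, against a mean of 0.02 and a test direction of down), interferon genes (-0.002, against a mean of 0.04 and a test direction of down) and hypoxia genes (-0.04, mean 0.02, test direction down) were close to 0. Markers of other cell types, namely T cell (6 genes, 0.05), myeloid (11 genes, 0.08), erythroid (4 genes, 0.22) and stromal genes (10 genes, 0.34), were not called either.

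**Figure D3:**
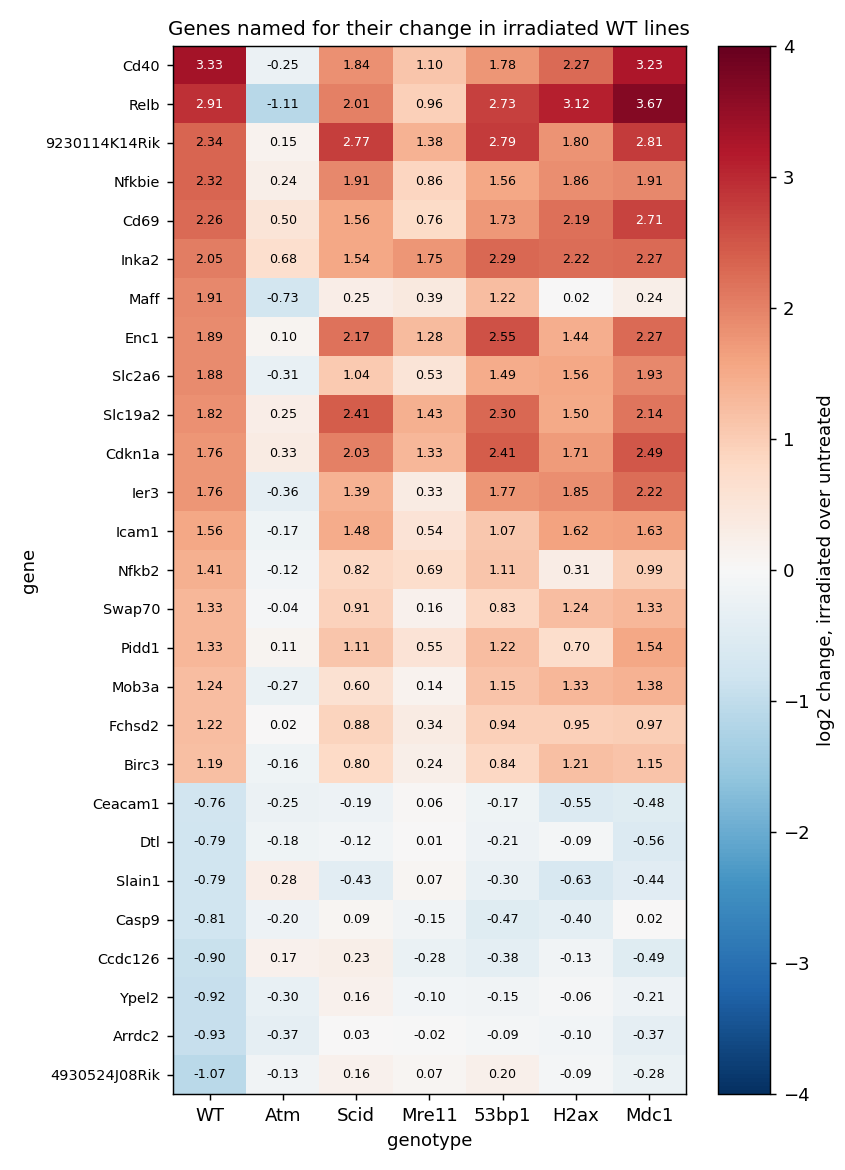
Log2 change after radiation (colour scale) of 27 genes named for WT lines, 1 per line of the grid, in the 7 genotypes along the horizontal axis. Cd40 ran from -0.25 in Atm-/- to 3.33 in WT lines and Cdkn1a from 0.33 in Atm-/- to 2.49 in Mdc1-/- lines.

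In Atm-/- lines neither the NF-kB nor the p53 list was called, although the p53 median was above 0 in each line (0.092 to 0.24). Relb changed by -1.11 ± 0.45, Cd40 by -0.25 and Cdkn1a by 0.33 (n = 3), none past the threshold. Ranbp1, a regulator of nuclear transport, was the 1 gene called, and it fell by 0.57 on the log2 scale (SE 0.10, adjusted p = 0.021; lower in 3 of 3 lines), against 734 genes at an unadjusted p under 0.05. This count was 24 without Atm irradiated replicate 1, 13 without untreated replicate 2, and 0 without irradiated replicate 2, untreated replicate 3 or irradiated replicate 3. Paired, 164 genes passed (64 higher, 100 lower), among them Tlr9, a receptor for bacterial DNA (1.95), Ubxn10 (1.97) and Arf5 (-1.21). Mir155hg, the host gene of an NF-kB-induced microRNA (-1.59), and the p53 target Bbc3 (0.89, adjusted p = 0.034) were also called. The paired count was 309 without Atm line 1, 260 without line 2 and 86 without line 3. G2/M genes alone among the lists moved, down by a median of -0.06 (adjusted p = 0.024, adjusted p = 0.742 with an estimated correlation), with line medians of -0.07, -0.22 and 0.15. The irradiated array of Atm line 2 and that of WT line 4 had higher median signals (116 and 103) than the other 40 arrays (62.6 to 82.9); without both, the Atm-/- count was 0 unpaired and 333 paired.

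In Scid lines, which lack DNA-PK activity, p53 and NF-kB targets rose and mitotic genes fell. Mdm2, the ubiquitin ligase that degrades p53, rose by 1.87 ± 0.27 (adjusted p = 0.00087, n = 3), Ddias by 2.10, Nfkbie by 1.91, Icam1 by 1.48 and Klhl26 by 1.44, while the spindle gene Tpx2 fell by 0.43 on the log2 scale. The 34 p53 targets had a median of 1.02 (adjusted p = 6.15e-21, adjusted p = 0.0165 with an estimated correlation), with 1 higher over all genes, 14 adjusted over the list alone and 18 when paired. NF-kB targets had a median of 0.64 (adjusted p = 3.49e-16; 2 over all genes, 9 adjusted over the list alone, 11 paired), and G2/M genes one of -0.22 (adjusted p = 3.85e-21; 1 lower over all genes, 9 adjusted over the list alone, 11 paired), and these 3 calls held with an estimated correlation. In total 9 genes passed (8 higher, 1 lower; 502 at an unadjusted p under 0.05) and 332 when paired (213 higher, 119 lower), including Fas, a death receptor (2.30), Bbc3 (1.52), Bcl2l11 (0.91), Plk1 (-0.62) and Rag1 (-1.05). The split of the unpaired calls was 10 higher and 2 lower after quantile normalization and 8 and 0 after centring on the 75th percentile. The count of 9 became 3 without Scid untreated or irradiated replicate 1, 2 without untreated replicate 3, 15 without irradiated replicate 2, 17 without Atm irradiated replicate 2, and 21 and 45 without H2ax irradiated replicates 1 and 2; Mdm2 alone of the 6 named genes passed without each Scid array. The paired count was 66 without line 1 and 213 without line 3. Homing (0.16, adjusted p = 0.0061, adjusted p = 0.128 with an estimated correlation), immediate-early (0.20, adjusted p = 0.0426, adjusted p = 0.612 with an estimated correlation) and apoptosis genes (median 0.006, mean 0.25, adjusted p = 0.0271, adjusted p = 0.132 with an estimated correlation) moved up.

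Mre11A/A lines had the fewest called genes. No gene passed unpaired with limma. An unadjusted p under 0.05 was reached by 137 genes, fewer than chance alone would give among 12363. Cd40 changed by 1.10, Sesn2 by 1.29, Polk by 1.15 and Mdm2 by 0.87 (n = 3). Paired, 4 genes rose, among them Cdkn1a (1.33, adjusted p = 0.0019), the thiamine transporter gene Slc19a2 (1.43 ± 0.52) and Kifc5b (0.89); the count was 1 without line 1 or line 3 and 0 without line 2. The p53 list rose by a median of 0.51 (adjusted p = 3.06e-18, adjusted p = 0.0234 with an estimated correlation), with 0 members over all genes and 1 adjusted over the list alone, or 1 and 17 when paired. NF-kB genes rose by 0.17 (adjusted p = 0.000139, adjusted p = 0.114 with an estimated correlation), with 0 members over all genes and 0 adjusted over the list alone. Apoptosis genes moved up (0.05, adjusted p = 0.012, adjusted p = 0.083 with an estimated correlation), and G1/S genes down (-0.07, adjusted p = 0.01, adjusted p = 0.612 with an estimated correlation).

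53bp1-/- lines responded in both p53 and NF-kB targets. Relb rose by 2.73 ± 0.45, Sesn2, a stress-induced p53 target, by 2.24 ± 0.36, and Mob3a by 1.15 ± 0.19 (adjusted p = 0.0033 each; n = 3), and these were the 3 calls, against 345 genes at an unadjusted p under 0.05. The count was 0 without 53bp1 untreated replicate 2, 13 without Scid irradiated replicate 1, and 16 and 42 without H2ax irradiated replicates 1 and 2. Of 240 paired calls, 188 were higher and 52 lower, including Plk2 (2.84), Cdkn1a (2.41), Fas (2.33), Bbc3 (1.78), Myc (-0.62) and Plk1 (-0.51); the count fell to 133, 80 and 109 without lines 1, 2 and 3. P53 targets had a median of 0.94 (adjusted p = 1.89e-29; 1 over all genes, 14 adjusted over the list alone, 21 paired), NF-kB targets 0.46 (adjusted p = 3.75e-17; 1, 8 and 13 in the same order) and G2/M genes -0.20 (adjusted p = 7.73e-17; 0, 2 and 6 lower), and these 3 calls held with an estimated correlation. Apoptosis genes rose by a median of 0.07 (adjusted p = 0.00143, adjusted p = 0.0311 with an estimated correlation, and 0.0657 when also paired), and G1/S genes fell by 0.08 (adjusted p = 0.0066, adjusted p = 0.593 with an estimated correlation; the median was 0.014 without 53bp1 irradiated replicate 1). Pre-B and B-cell genes were called lower when paired (adjusted p = 0.0202, adjusted p = 0.351 with an estimated correlation).

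In H2ax-/- lines NF-kB targets rose and mitotic genes fell. Relb rose by 3.12 ± 0.45 (adjusted p = 0.00041, n = 3), Cd40 by 2.27, Cd69 by 2.19, Nfkbie by 1.86, Tnfaip3, a feedback inhibitor of NF-kB, by 1.78, Icam1 by 1.62, Mob3a by 1.33, Swap70 by 1.24 and Birc3 by 1.21. Plk1, the mitotic kinase, fell by 0.77 and Tpx2 by 0.46 on the log2 scale (adjusted p = 0.016 each). These were the 11 calls (379 at an unadjusted p under 0.05). Their number was 5, 4 and 7 without H2ax untreated replicate 1, irradiated replicate 1 and irradiated replicate 3, 4 without untreated replicate 3, and 47 without irradiated replicate 2. Paired, 244 genes passed, 130 higher and 114 lower, with Bcl3 (2.40), Cdkn1a (1.71), Rag1 (-1.17), Rag2 (-1.11) and Hes5 (-1.16) among them; quantile normalization gave 146 and 109, and centring on the 75th percentile 136 and 64. That count was 50 without line 1 and 63 without line 3. NF-kB targets had a median of 0.43 (adjusted p = 8.94e-24; 6 over all genes, 10 adjusted over the list alone, 12 paired), G2/M genes -0.22 (adjusted p = 2.32e-20; 2, 9 and 11 lower) and p53 targets 0.70 (adjusted p = 8.73e-14, adjusted p = 0.0519 with an estimated correlation and 0.0277 when also paired; 0, 4 and 16 higher). The p53 median was 0.14 in H2ax line 2, against 1.01 and 0.99 in lines 1 and 3. Homing genes moved up by 0.02 unpaired (adjusted p = 0.0145, adjusted p = 0.191 with an estimated correlation, paired adjusted p = 0.0516), and immediate-early genes when paired (adjusted p = 0.0392, adjusted p = 0.374 with an estimated correlation).

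Mdc1-/- lines had the largest count, 78 genes unpaired (71 higher, 7 lower; 642 at an unadjusted p under 0.05) and 707 paired (394 and 313). Relb rose by 3.67 ± 0.45 (adjusted p = 2.7e-05, n = 3), Cd40 by 3.23 and Cd69 by 2.71, and the p53 targets Sesn2 by 2.21, Bbc3 by 2.06, Polk by 1.93, Mdm2 by 1.54, Pidd1 by 1.54 and Apaf1, the scaffold of the apoptosome, by 0.75. Among mitotic genes, Cenpe fell by 0.74, Cenpf by 0.73, Plk1 by 0.70, Aurka by 0.51 and Tpx2 by 0.45 on the log2 scale. The unpaired count was 50, 28 and 23 without Mdc1 untreated replicate 1, untreated replicate 2 and irradiated replicate 3, and 9 of its 22 named genes, Sesn2 and Mdm2 among them, passed without each Mdc1 array. The paired count was 393 without line 2 and 310 without line 3, and it added Fas (2.96), Cdkn1a (2.49), Rag1 (-1.41), Rag2 (-1.35), Myc (-0.79) and Cdc6 (-0.57). P53 targets had a median of 1.18 (adjusted p = 4.44e-27; 7 higher over all genes, 16 adjusted over the list alone, 23 paired), NF-kB targets 0.56 (adjusted p = 1.07e-25; 6, 13 and 16) and G2/M genes -0.32 (adjusted p = 2.58e-22; 6, 13 and 16 lower), and all 3 held with an estimated correlation. Apoptosis (median 0.04, mean 0.37, adjusted p = 0.00527, adjusted p = 0.0519 with an estimated correlation), homing (median 0.07, mean 0.37, adjusted p = 0.000747, adjusted p = 0.0524 with an estimated correlation) and G1/S genes (-0.07, adjusted p = 0.0188, adjusted p = 0.636 with an estimated correlation) were also called. Immediate-early genes were called up when paired (adjusted p = 0.0236, adjusted p = 0.351 with an estimated correlation). Weaker probe sets of Tpx2 and Aurka changed by 0.19 and 0.32.

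**Figure D4:**
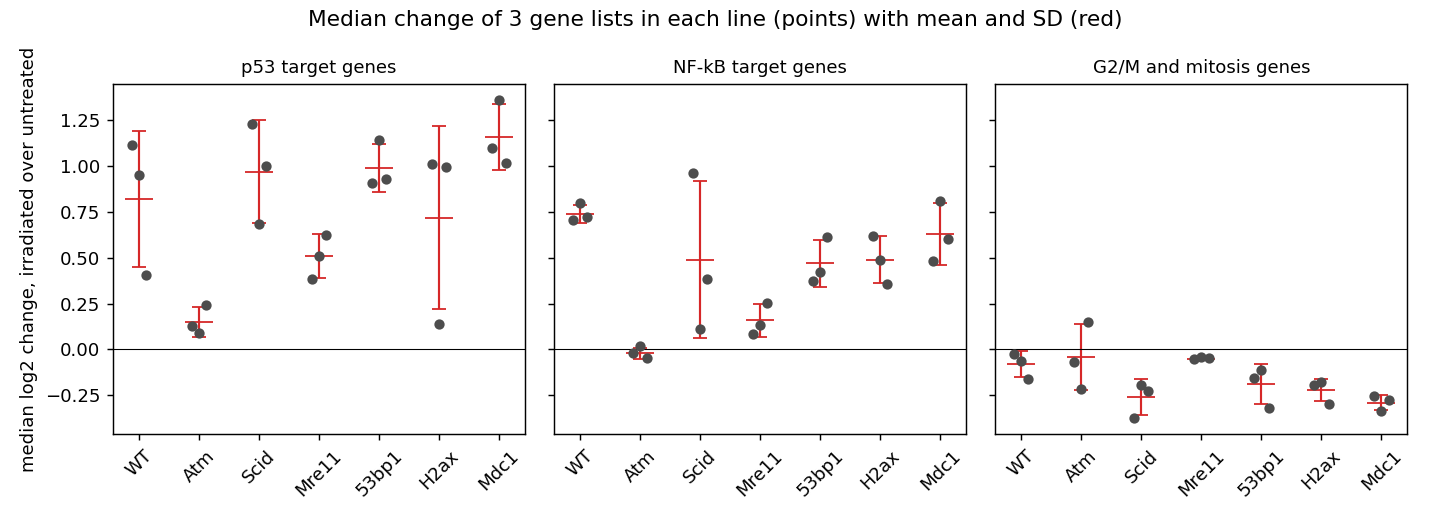
Median log2 change after radiation (vertical axis) of the p53, NF-kB and G2/M lists, in 1 panel each, for every line (points), with the mean ± SD of the 3 lines of a genotype in red. NF-kB medians were 0.74 ± 0.05 in WT, -0.02 ± 0.03 in Atm-/- and 0.49 ± 0.43 in Scid lines, and p53 medians 0.82 ± 0.37 in WT and 0.15 ± 0.08 in Atm-/- lines.

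When the radiation response of each mutant was tested against that of WT lines, Atm-/- lines differed most. Relb (-4.02 ± 0.63, adjusted p = 0.0046), Cd40 (-3.58 ± 0.62, adjusted p = 0.011) and Mob3a (-1.51 ± 0.27, adjusted p = 0.011) responded less than in WT lines (n = 3 lines each), out of 598 genes at an unadjusted p under 0.05. Paired, 256 genes differed (126 higher, 130 lower), among them the NF-kB targets Nfkbie (-2.08), Icam1 (-1.73) and Birc3 (-1.35), Mir155hg (-3.19), Slc2a6 (-2.19), Cd69 (-1.76), and the p53 targets Mdm2 (-1.19), Pidd1 (-1.22) and Aen (-0.94). The 3 unpaired calls became 1 without WT untreated replicate 1, WT irradiated replicate 3 or Atm irradiated replicate 3, and 8 and 5 without Scid irradiated replicates 1 and 2. The 256 became 65, 25 and 596 without WT lines 1, 3 and 4 and 137 without Atm line 1. NF-kB targets responded less by a median of -0.83 (adjusted p = 1.16e-15, adjusted p = 0.00362 with an estimated correlation and 0.206 when also paired; 2 over all genes, 10 adjusted over the list alone, 12 paired). P53 targets responded less by -0.63 (adjusted p = 5.78e-06, adjusted p = 0.734 with an estimated correlation; 0 members adjusted over the list alone, and 7 lower and 1 higher when paired) and homing genes by -0.25 (adjusted p = 0.00895, adjusted p = 0.596 with an estimated correlation). Each of these comparisons shares the WT arrays with the others. In Atm line 2 Cdkn1a was low before radiation too (296, against 1337 and 1756 in lines 1 and 3). It changed by 0.47, 0.13 and 0.39 in Atm lines 1, 2 and 3. Whether line 2 lacked a p53 response for a reason other than Atm was not tested.

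For the other mutants, limma called 0 genes against WT unpaired, with 203 (Scid), 260 (Mre11A/A), 189 (53bp1-/-), 152 (H2ax-/-) and 165 (Mdc1-/-) at an unadjusted p under 0.05. Each of these numbers lay below what chance alone would give among 12363 genes. Paired, Mre11A/A lines differed in Mob3a (-1.10, adjusted p = 0.04) and Scid lines in Igk, an immunoglobulin light chain (-2.05, adjusted p = 0.042), while 0 genes were called for the other three, with 651, 561 and 637 at an unadjusted p under 0.05. The call for Igk was lost without WT line 4 or Scid line 3 (0 genes each), and that for Mob3a without WT line 3 or Mre11 line 2 (0 genes each). Without H2ax line 1 or 2, 1 gene was called for H2ax-/- lines. NF-kB targets responded less in Mre11A/A (-0.64, adjusted p = 5.44e-11, adjusted p = 0.017 with an estimated correlation and 0.206 when also paired), Scid (-0.24, adjusted p = 0.0294, adjusted p = 0.734 with an estimated correlation) and 53bp1-/- lines (-0.21, adjusted p = 0.00818, adjusted p = 0.734 with an estimated correlation). The Scid value rested on lines 2 and 3 (medians 0.11 and 0.38), since line 1 (0.96) responded more than each WT line (0.71 to 0.80). G2/M genes fell further than in WT in Scid (-0.17), 53bp1-/- (-0.12), H2ax-/- (-0.12) and Mdc1-/- lines (-0.21, adjusted p = 2.63e-09), with adjusted p = 0.734, 0.979, 0.734 and 0.596 with an estimated correlation. P53 targets responded more in Mdc1-/- lines (0.34, adjusted p = 0.00168, adjusted p = 0.823 with an estimated correlation; WT line 4 had the lowest median of the WT lines, 0.41) and, when paired, more in 53bp1-/- (0.27, adjusted p = 0.00847) and less in Mre11A/A lines (-0.26, adjusted p = 0.0151), both at adjusted p = 0.923 with an estimated correlation. Homing genes responded less in Mre11A/A (-0.15, adjusted p = 0.0212) and 53bp1-/- lines (-0.18, adjusted p = 0.0196), both at adjusted p = 0.596 with an estimated correlation, and G1/S genes fell less in H2ax-/- lines (0.07, adjusted p = 0.0212, adjusted p = 0.979 with an estimated correlation; the median was -0.023 without WT irradiated replicate 4). Paired calls were added for G1/S genes in Atm-/- (adjusted p = 0.026), G2/M genes in Mre11A/A (adjusted p = 0.0464), pre-B and heat shock genes in 53bp1-/- (adjusted p = 0.026 each) and hypoxia genes in H2ax-/- lines (adjusted p = 0.0301). These had adjusted p = 0.883, 0.923, 0.586, 0.493 and 0.493 with an estimated correlation, in the same order. Of the 96 list comparisons with WT, 14 were called, 9 without WT untreated replicate 1, and 21 when paired.

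Many genes called in WT lines when paired were also called in the same direction in Mdc1-/-, Scid, 53bp1-/- and H2ax-/- lines. Of the paired calls, 290 were shared with Mdc1-/-, 197 with Scid, 158 with 53bp1-/-, 156 with H2ax-/-, 3 with Mre11A/A and 3 with Atm-/- lines. Another 7 were called in opposite directions in Atm-/- and WT lines, and 0 in the other mutants. Independent lists would share 7.87 higher and 5.52 lower genes for Mdc1-/- and 1.28 and 1.76 for Atm-/- lines. Unpaired, 10, 2, 2, 8, 0 and 0 were shared in the same order. Of the 465 paired WT genes, 95.7% changed in the same direction in Mdc1-/-, 94% in Scid, 96.3% in 53bp1-/-, 95.1% in H2ax-/-, 75.7% in Mre11A/A and 52.3% in Atm-/- lines. Leaving out WT line 1 gave 147, 99, 91 and 98 shared genes for Mdc1-/-, Scid, 53bp1-/- and H2ax-/- lines, and WT line 3 gave 92, 71, 69 and 72. The lowest counts without a mutant line were 191 (Mdc1 line 2), 56 (Scid line 1), 70 (53bp1 line 2) and 35 (H2ax line 1). For Atm-/- lines the count ranged from 1 (without WT line 3) to 18 (without Atm line 1), and for Mre11A/A lines from 0 (without Mre11 line 1 or 2) to 13 (without WT line 4).

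Among the 6 mutants, the response of Relb (adjusted p = 0.00132) and Mob3a (adjusted p = 0.00323) differed between genotypes in limma's F test, 2 genes (5 without Scid irradiated replicate 1) against 143 when paired. The paired genes included Cdkn1a, Nfkbia, the NF-kB inhibitor gene, Pvt1, a p53-responsive transcript beside Myc, Btg2, an antiproliferative p53 target, and the mitotic genes Cenpf and Aspm. Nfkbia changed by -0.14 in Atm-/-, 0.21 in Mre11A/A, 0.73 in Scid and 0.94 in H2ax-/- lines, and Aspm by -0.05, 0.05, -0.51 and -0.36. Over the 15 pairs of mutants, 5 differences were called, and 311 when paired, of which 273 involved Atm-/- lines (117 against Mdc1-/-, 66 against Scid, 49 against H2ax-/-, 36 against 53bp1-/- and 5 against Mre11A/A). Mre11A/A lines differed from Mdc1-/- lines in 16 genes, including Mob3a, Aspm, Cenpf, Bcl3 and Cd69, and from H2ax-/- lines in 9, including Nfkbia and Plk1. The paired F count was between 64 and 95 without Atm line 3, Mre11 lines 1 or 2, 53bp1 line 2 or Mdc1 lines 2 or 3, and the 5 pairwise calls were between 1 and 11 without a single array.

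Untreated mutant lines were compared with untreated WT lines, which all 6 comparisons share. In Atm-/- lines, Atm fell by 2.23 on the log2 scale (adjusted p = 3.9e-07), and Zscan12 (-2.31), Spata13 (-1.24), Arcn1 (-0.62) and Lcp1 (-0.61) were lower, while Ccnb1ip1, a meiotic crossover ligase, was higher by 4.77. This made 9 genes (3 higher, 6 lower, with 1245 at an unadjusted p under 0.05), 19 when lines were blocked, and 3 to 32 without a single array. Ccnb1ip1 was also called against the same WT arrays in untreated Scid, H2ax-/- and Mdc1-/- lines. In Scid lines 49 genes passed (25 higher, 24 lower), 81 with blocking, led by AI506816 (5.03), Cpne8 (3.79), Abca1, the cholesterol exporter (2.86), and Coro2a (-3.92). Runx1, a transcription factor of blood development, fell by 2.32, although its other probe sets changed by 0.05 and 0.18, and Pdxdc1 fell by 3.48 while another of its probe sets changed by 4.71. The Scid count was 17, 23 and 25 without WT replicate 1, WT replicate 3 and Scid replicate 2. Pgk1, a glycolytic enzyme and hypoxia target, was higher (0.56), and Kif20a, a mitotic kinesin, lower (-1.01).

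In untreated Mre11A/A lines 299 genes passed (178 higher, 121 lower), in 53bp1-/- lines 362 (199 and 163), in H2ax-/- lines 505 (308 and 197) and in Mdc1-/- lines 614 (371 and 243). Gnai1, an inhibitory G-protein subunit, was higher by 5.52 in Mre11A/A, 6.05 in 53bp1-/- (23.7 in WT and 2629 there) and 6.04 in Mdc1-/- lines, and the sialyltransferase St6galnac2 by 5.56, 5.34 and 5.64 in 53bp1-/-, H2ax-/- and Mdc1-/- lines. Clec2d, a lectin-like NK-receptor ligand, was higher in Mre11A/A lines (2.94), and Xist, transcribed from the inactive X chromosome, was lower (-6.07), in a genotype with 2 lines of male type. Mgst1 was higher in 53bp1-/- (3.81) and H2ax-/- lines (4.14), B3galt1 was lower in 53bp1-/- (-2.98) and Mdc1-/- lines (-2.99), and Sdc4 fell by 2.86 in 53bp1-/- lines, where another probe set changed by 1.44. Rpgrip1 was lower in H2ax-/- (-2.57, with other probe sets at 0.24 and 0.04) and Mdc1-/- lines (-4.79). Targeted genes were among the calls: H2ax (-7.42), Mdc1 (-2.94), Mre11a (-1.44) and Trp53bp1 (-0.63, adjusted p = 0.03, with other probe sets from -1.14 to 0.21). Trp53bp1 was higher in Mdc1-/- lines (0.67). Over untreated and irradiated arrays together, another of its probe sets read 733 in WT (599 to 903) and 1137 in Mdc1-/- lines (1039 to 1311). Weaker sets at 125 and 118 in WT read 209 and 146 there. Sets near background, at 38.8 and 41.0 in WT, read 8.71 and 9.93 there, and weaker sets changed by -1.07 and -0.76 in untreated lines. The hybridization control BioB, added in equal amounts to each sample, read 521 to 779 (median 636) on the 18 arrays of WT, Atm-/- and Scid lines and 354 to 552 (median 494) on the 24 arrays of these 4 genotypes, and the probe set for 18S ribosomal RNA read 298 to 2387 and 126 to 284.

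Counts of untreated differences were lower without single arrays of the groups compared, which also leaves fewer arrays to compare. Without WT replicate 3 they were 165 (Mre11A/A), 175 (53bp1-/-), 274 (H2ax-/-) and 382 (Mdc1-/-), and without WT replicate 4 they were 240, 263 and 340 for the last 3. Leaving out Mre11 replicate 2 or 3 gave 147 and 181, 53bp1 replicate 1 or 2 gave 172 and 230, H2ax replicate 1, 2 or 3 gave 267, 238 and 257, and Mdc1 replicate 2 or 3 gave 377 and 276. Of the 96 list comparisons, 9 were called, and each had adjusted p = 0.994 with an estimated correlation. P53 targets (-0.24, adjusted p = 0.00966) and interferon genes (-0.26, adjusted p = 0.00438) were lower and hypoxia genes higher (0.23, adjusted p = 0.014) in Atm-/- lines. The untreated p53 median was lowest in Atm line 2 (8.44, against 9.02 and 9.25 in lines 1 and 3 and 9.10 to 9.56 in WT lines), and the interferon median in Atm line 1 (8.14, against 8.56 and 8.61). Scid lines had lower G2/M (-0.10, adjusted p = 0.0026) and G1/S genes (-0.14, adjusted p = 0.00215) and higher hypoxia genes (0.36, adjusted p = 0.000727), but the median level of Scid line 1 (11.08) lay within that of WT lines (11.07 to 11.18). Mre11A/A lines had higher G2/M genes (0.15, adjusted p = 0.0156), with Ube2c (0.56) and Cdc25b (0.65) among them, and lower hypoxia genes (-0.23, adjusted p = 0.00459), although the median level of Mre11 line 1 (11.41) lay above WT. In Mdc1-/- lines heat shock and unfolded-protein genes were lower (-0.19, adjusted p = 0.014; median levels of single lines, 10.90 to 11.12, overlapped with WT), including Trib3 (-1.83), Hspa5 (-0.54) and Dnajb1 (-0.50).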

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

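The comparison of control probe sets between sets of arrays, the comparison of both Atm probe sets, the test of genes between H2ax and Atm and the splits that move whole lines between genotypes were chosen only after the results they bear on had been seen; the other tests in this part were set beforehand.

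The radiation response differed from that of WT lines in Atm-/- lines for 3 genes unpaired and 256 paired, by limma's test of the difference. Named among them were Relb (-4.02), Cd40 (-3.58), Mir155hg (-3.19), Maff (-2.65), 9230114K14Rik (-2.19), Slc2a6 (-2.19), Nfkbie (-2.08), Pilrb1 (-2.08), Oas1b (-2.0), Enc1 (-1.79) and Mob3a (-1.51). Paired, 1 gene differed in Mre11A/A lines, Mob3a (-1.10), and 1 in Scid lines, Igk (-2.05). Among the mutants, 2 genes differed unpaired and 143 paired, and 5 and 311 differences between pairs of mutants were called.

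Gene lists also responded differently from WT. In Atm-/- lines p53 targets responded by -0.63, NF-kB targets by -0.83 and homing genes by -0.25 relative to WT. NF-kB targets responded less in Mre11A/A (-0.64), Scid (-0.24, but more than in each WT line in Scid line 1) and 53bp1-/- lines (-0.21), and homing genes less in Mre11A/A (-0.15) and 53bp1-/- lines (-0.18). G2/M genes fell further in Scid (-0.17), 53bp1-/- (-0.12), H2ax-/- (-0.12) and Mdc1-/- lines (-0.21). G1/S genes fell less in H2ax-/- lines (0.072), and p53 targets responded more in Mdc1-/- lines (0.34). With an estimated correlation the NF-kB lists of Atm-/- and Mre11A/A lines held their unpaired call and the other 12 did not; paired, both lost it (adjusted p = 0.206 each with an estimated correlation).

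Other splits of the arrays were made in 2 ways. Exchanging treated and untreated arrays within genotypes also turns the common response around, so it does not model equal responses of 2 genotypes, and it leaves open whether chance made these differences. For Atm-/- against WT, 45 of 100 such unpaired splits called at least the 3 real genes (highest other 253) and 6 of 32 paired swaps at least the real 256 (highest other 391). For Scid the 1 paired call was reached in 9 of 32 swaps (highest other 904) and for Mre11A/A the 1 paired call in 8 (highest other 274). For 53bp1-/-, H2ax-/- and Mdc1-/- lines limma called 0 genes paired (651, 561 and 637 at an unadjusted p under 0.05), and a count of 0 is reached by every split, here 32 of 32, and so tells nothing (highest others 742, 883 and 1251). The same holds for the unpaired counts of 0, reached by all 100 splits (highest others 93 for Scid, 16 for Mre11A/A, 104 for 53bp1-/-, 65 for H2ax-/- and 45 for Mdc1-/-). The highest paired values of Scid, Mre11A/A, 53bp1-/-, H2ax-/- and Mdc1-/- lines came from exchanging a whole genotype, which by construction sets opposite responses against each other. Without that exchange the highest were 334, 92, 203, 284 and 553.

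Splits that move whole lines between a mutant and WT keep the treatment of each line, but number 10, too few for a share under 0.05. Real and highest other counts were 3 and 2 for Atm-/- lines unpaired (reached by 1 of 10) and 256 and 467 paired (2 of 10). For the 1 paired call of Scid lines the highest other was 13 (reached by 4 of 10) and for that of Mre11A/A lines 0 (1 of 10). The counts of 0 were reached by all 10 splits and tell nothing, with highest others of 2 for Scid, 1 for Mre11A/A and 0 for the other 3 unpaired, and 75, 0 and 0 for 53bp1-/-, H2ax-/- and Mdc1-/- lines paired.

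Splits that move whole lines among the 6 mutants can be drawn often enough. The 2 genes that differed among mutants unpaired were reached by 2 of 100 (highest other 2) and the 143 paired genes by 1, the real one (highest other 58). The 5 unpaired differences between pairs of mutants were reached by 1 of 100 (highest other 1) and the 311 paired ones by 1 (highest other 100). Chance thus rarely gave as much for the 2 paired counts. Unpaired, a group of reassigned lines mixes genotypes, and their differences in level add to the spread, which can lower the counts of the other reassignments. The unpaired splits therefore do not decide whether chance gave the 2 genes and 5 differences, and another reassignment did reach the 2 genes. With lines moved among all 7 genotypes, the 14 list calls against WT were reached by 21 of 100 splits (highest other 28) and the 21 paired ones by 16 (highest other 34), so chance cannot be excluded for their number. Exchanged treatments, which leave it open here too, reached the 2 and 143 genes in 26 and 3 of 100 splits (highest others 107 and 533), the 5 and 311 differences in 27 and 3 (highest others 185 and 1431), and the 14 and 21 lists in 52 and 25 (highest others 32 and 28). Splits with several times the real count were among those that turn the common response around, and no other source of their counts was tested.

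More genes differed from WT in untreated Mre11A/A, 53bp1-/-, H2ax-/- and Mdc1-/- lines (299 to 614) than in Atm-/- and Scid lines (9 and 49). Dividing the untreated arrays into these 4 genotypes and the other 3 gave 2289 genes, against at most 1412 for the other 34 divisions into 3 and 4 genotypes. This division was taken from the counts of the same untreated arrays, so its lead largely restates them and decides nothing about its source. The 1412 came from the same division with Mre11A/A lines moved, and divisions whose smaller side mixed both sets gave at most 194. A batch of arrays shared by WT, Atm-/- and Scid lines could be the source, since 18S ribosomal RNA signal did not overlap between both sets and both hybridization controls tested were shifted. BioB had medians of 636 and 494 and CreX of 34230 (26920 to 38440) and 26930 (19000 to 30680), although 0 of the 2 were free of overlap. Batch and genotype cannot be told apart. A shared genetic background of the animals would give the same division and was not tested. Comparisons within a set gave 9 to 256 genes among WT, Atm-/- and Scid lines and 25 to 122 among the other 4, against 299 to 1470 between the sets.

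An Atm probe set read lower than WT in H2ax-/- (log2 difference -2.28) and Mdc1-/- lines (-2.36). The other kept Atm probe set differed by 0.22 and 0.06 there, neither past the threshold, which is consistent with a sequence variant or an alternative transcript end under the first probe set and argues against a general loss of Atm transcript. A linked stretch of chromosome around the targeted gene is argued against for Mdc1, which lies on chromosome 17 while Atm lies on chromosome 9 (Fisher's exact p = 1 for called genes near Mdc1). For H2ax, Atm lies outside the 200 nearest genes (Fisher's exact p = 0.29 there), which argues against a stretch of that length. This bound, set before the test was run, was too short to exclude a longer one, because both genes lie on chromosome 9 with 207 genes between them. Of the 60 tested genes between them 4 were called (6.67%, against 4.06% elsewhere; Fisher's exact p = 0.31), so a stretch from H2ax to Atm stays open. No array sequence was looked at, and lower Atm transcript of 1 form was not tested.

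Cdkn1a in H2ax line 2 went from 216 to 460 after radiation, against 2196 to 9697 in line 1. A failed irradiation or a poor array is argued against, because NF-kB targets in this line changed by a median 1.36 times that of the lower of the other lines. Without Cdkn1a, the p53 targets changed by 0.11 times that of the lower of the other lines (a median of 0.11, against 1.01 and 0.99 in lines 1 and 3), which is consistent with a reduced p53 response of this line. Ccng1, another p53 target, went from 2872 to 3023 and Mdm2 from 1084 to 1221. Selection for loss of p53 function during transformation may be a biological source, and no p53 sequence was looked at.

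Of the 5015 kept probe sets without a single gene name, which entered none of the comparisons, limma called 0 unpaired after radiation in WT, Atm-/-, Mre11A/A, 53bp1-/- and H2ax-/- lines (299, 341, 115, 122 and 156 at an unadjusted p under 0.05), 6 in Scid and 2 in Mdc1-/- lines. Paired calls numbered 37 in WT, 48 in Atm-/-, 41 in Scid, 2 in Mre11A/A, 34 in 53bp1-/-, 25 in H2ax-/- and 81 in Mdc1-/- lines.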

How the results depend on the processing

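Leaving out the arrays with raised low signals, and each alternative for the paired comparison, were chosen after the data were examined; the other alternatives were not. In general the direction of named genes held and their number did not. The direction had little room to change, since many genes were named because their arrays did not overlap. The line as a block also leaves their log2 changes as they were. Of the 126 calls for genes named unpaired, 0 reversed in limma under any alternative, 126 kept their call with the line as a block and 51 when fitted to only the arrays compared; over the 774 repeats without 1 array of the comparison, 479 kept it. Of 213 paired calls 162 kept it with no intensity trend and 190 to 208 with the other settings (of 190 under the stricter filter, 190), and 497 of 699 did without 1 line. Of the 54 called lists, 54 kept their call after centring on the 75th percentile, 17 with an estimated correlation, 16 with fry, 53 with the block, and 316 of 408 without 1 array. A gene below a filter gives no value, and signal near background limits what low genes can show. The cause was not tested for any change given here, except that fewer arrays leave fewer degrees of freedom.

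With the line as a replicate block, calls after radiation went from 12 to 465 in WT, 1 to 164 in Atm, 9 to 332 in Scid, 0 to 4 in Mre11, 3 to 240 in 53bp1, 11 to 244 in H2ax and 78 to 707 in Mdc1 lines. Those against WT went from 3 to 256 (Atm), 0 to 1 (Scid) and 0 to 1 (Mre11). Calls shared with WT went from 0 to 3 (Atm), 2 to 197 (Scid), 0 to 3 (Mre11), 2 to 158 (53bp1), 8 to 156 (H2ax) and 10 to 290 (Mdc1). Genes that differed among mutants went from 2 to 143 and pairwise differences from 5 to 311. Untreated calls went from 9 to 19 (Atm) and 49 to 81 (Scid). For the other untreated counts the block kept 272 of 299 calls (Mre11), 331 of 362 (53bp1), 453 of 505 (H2ax) and 556 of 614 (Mdc1), and for those of Atm and Scid it kept 9 of 9 and 42 of 49.

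Fitted with limma to only the arrays compared, the unpaired counts were 0 (WT), 0 (Atm), 3 (Scid) and 25 (53bp1) after radiation, 0 for Atm against WT, 0 shared calls for each of Scid, 53bp1, H2ax and Mdc1, 0 pairwise differences, and 0, 2, 104, 77, 251 and 323 untreated (Atm, Scid, Mre11, 53bp1, H2ax, Mdc1). Over every kept probe set they were 23, 2 and 21 after radiation (WT, Atm, Scid), 5 and 18 shared (Scid, Mdc1), 2 pairwise, and 29, 144, 1408, 1472, 1612 and 2124 untreated, in part because more features were counted. A pseudocount of 1 gave 4 for Atm after radiation and 15 untreated, and one of 64 gave 14 for Scid. Without the filter, Atm had 2 after radiation, 5 against WT and 5 untreated, and pairs 2. At the 70th percentile, Atm had 3 after radiation and Scid 81 untreated. Centring on the 75th percentile gave 0 for Atm after radiation and 26 for untreated Scid lines. Without the intensity trend, Atm had 0 after radiation and 5 untreated, and Scid 27 untreated. Without both arrays with raised low signals, Atm had 0 and Scid 18 after radiation, 4 calls were shared by Scid and WT, 1 pairwise difference was called, 24 and 87 genes were called in untreated Atm and Scid lines, and 8 lists differed from WT. With an estimated correlation 15 lists were called after radiation, 2 against WT and 0 untreated, and with fry 15, 1 and 2. Paired, the estimated correlation gave 15 lists after radiation and 0 against WT.

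Paired, without the intensity trend, counts after radiation were 263 (WT), 50 (Atm), 195 (Scid), 0 (Mre11), 131 (53bp1) and 116 (H2ax). Against WT they were 33 (Atm), 0 (Mre11) and 1 (53bp1), those shared with WT 0 (Atm), 92 (Scid), 0 (Mre11), 79 (53bp1), 68 (H2ax) and 165 (Mdc1), and those among mutants 11 and 23 (pairs). Without the lines with raised signals, Atm had 333 and Mre11 17 after radiation, Atm 552, Scid 0 and Mre11 4 against WT, Atm 5 and Mre11 13 shared, and pairs 531. Every kept probe set gave 358 (Atm) and 13 (Mre11) after radiation, 0 (Scid) and 0 (Mre11) against WT and 12 shared (Mre11). The stricter filter gave 7 for Mre11, and 7 (Atm) and 5 (Mre11) shared. The single Scid call against WT became 0 with a pseudocount of 64, without the filter and after quantile normalization, and the single Mre11 call 0 with a pseudocount of 1 and after quantile normalization.

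Without 1 array, counts after radiation ranged from 4 to 31 (WT), 0 to 24 (Atm), 2 to 45 (Scid), 0 to 42 (53bp1), 4 to 47 (H2ax) and 23 to 104 (Mdc1), and from 1 to 8 for Atm against WT. Untreated counts ranged from 3 to 32 (Atm), 17 to 65 (Scid), 147 to 343 (Mre11), 172 to 423 (53bp1), 238 to 573 (H2ax) and 276 to 678 (Mdc1). Shared counts ranged from 0 to 17 (Scid), 0 to 18 (53bp1), 4 to 21 (H2ax) and 4 to 27 (Mdc1), those among mutants from 2 to 5 and from 1 to 11 (pairs), and lists against WT from 9 to 19. With 1 line left out of the paired comparison, in which the lines that remain are assumed to vary like the other groups, the ranges were 114 to 387 (WT), 86 to 309 (Atm), 66 to 326 (Scid), 0 to 1 (Mre11), 80 to 133 (53bp1), 50 to 212 (H2ax) and 310 to 489 (Mdc1). Against WT they were 25 to 596 (Atm), 0 to 3 (Scid), 0 to 3 (Mre11) and 0 to 1 (H2ax). Shared counts ranged from 1 to 18 (Atm), 56 to 194 (Scid), 0 to 13 (Mre11), 69 to 158 (53bp1), 35 to 164 (H2ax) and 92 to 255 (Mdc1), those among mutants from 64 to 169 and from 137 to 448 (pairs), and lists against WT from 15 to 26.

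The list of G1/S genes reversed: its median of -0.08 in 53bp1 lines became 0.014 without 53bp1 irradiated replicate 1 (range without 1 array -0.13 to 0.014). Its median of 0.07 in H2ax lines against WT became -0.023 without the arrays with raised low signals and -0.023 without WT irradiated replicate 4 (range -0.023 to 0.132).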

Other observations

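The tests of chromosome neighbours and the splits in this part were set before their results were seen; the genes given for single lines were chosen after their values were seen.

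Single genes of B cells and of the heat shock response changed in some genotypes. Paired, Rag1 fell in WT (-1.15), Scid (-1.05), 53bp1-/- (-0.85), H2ax-/- (-1.17) and Mdc1-/- lines (-1.41), while Rag1 changed by -0.25 in Atm-/- and -0.20 in Mre11A/A lines without passing. The list of pre-B and B-cell genes was called unpaired in 0 genotypes. Spib, a transcription factor of B cells, rose by 1.52 in WT, 1.40 in Scid and 1.36 in Mdc1-/- lines, and changed by 0.03 in Atm-/- lines. The heat shock gene Hspa1b rose in WT (1.45), H2ax-/- (1.65) and Mdc1-/- lines (1.76) when paired. Differences of these genes between genotypes are not claimed here.

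Levels of p53 pathway genes differed widely between lines of a genotype. Untreated Cdkn1a read 216 in H2ax line 2 and 296 in Atm line 2, against 1321 or more in the WT lines. Zmat3 read 76.4 in Atm line 2, against 1753 and 1810 in Atm lines 1 and 3. Cdkn2a, the Arf and p16 gene, read 2754 in H2ax line 2, 6065 in Atm line 2 and 2849 in WT line 4. In Scid lines the median NF-kB response was 0.96, 0.11 and 0.38 in lines 1, 2 and 3.

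Genes on the chromosome around a targeted gene can differ because they come with the allele from another mouse strain. Among the 200 nearest genes, 8 of 92 tested (8.7%) were called in untreated 53bp1-/- lines, against 2.88% elsewhere (two-sided Fisher's exact test, adjusted p = 0.0324 over the 6 mutants), which is consistent with such a flanking stretch. The 8 were Cops2, Dnajc17, Hypk, Mga, Rmdn3, Rpusd2, Serf2 and Vps39. In Scid lines 2 of 79 were called, Nde1 and Pdxdc1 (2.53% against 0.383%, adjusted p = 0.117), and in H2ax-/- lines 4 of 56, Arcn1, Dpagt1, Sc5d and Scn2b (adjusted p = 0.58), so that the explanation stays open for both. Arcn1 was also lower in untreated Atm-/- lines (-0.62), whose targeted gene lies on the same chromosome. Atm-/-, Mre11A/A and Mdc1-/- lines had 0 of 65, 0 of 35 and 3 of 66 called (adjusted p = 1 each), with no excess seen. The shares elsewhere were 0.0651%, 2.42% and 4.96%. With so few calls elsewhere and so few neighbours tested, the counts of 0 say little about a flanking stretch in Atm-/- and Mre11A/A lines.

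For the radiation response of a single genotype, 3 against 3 arrays make 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 12 and 10 in WT, 1 and 678 in Atm-/-, 9 and 90 in Scid, 0 and 2 in Mre11A/A (limma, 137 at an unadjusted p under 0.05), 3 and 19 in 53bp1-/-, 11 and 23 in H2ax-/- and 78 and 1 in Mdc1-/- lines. Splits that part both arrays of every line, as the real one does, gave at most 2 genes in Atm-/- and 0 in the other genotypes, and the large counts came from splits that keep lines together and so point to differences between lines. As many genes as the real split were called by 8 of 10 splits in Atm-/-, 5 in Scid, 10 in Mre11A/A, 3 in 53bp1-/-, 3 in H2ax-/-, and 1 in WT and Mdc1-/- lines. Paired, exchanging both arrays within lines gives 4 arrangements, again too few. The real and highest other counts were 465 and 3 in WT, 164 and 23 in Atm-/-, 332 and 2 in Scid, and 4, 240, 244 and 707 against 0 in Mre11A/A, 53bp1-/-, H2ax-/- and Mdc1-/- lines. For untreated lines, also with 10 splits, they were 9 and 2 (Atm-/-), 49 and 1 (Scid), and 299, 362, 505 and 614 against 0 for Mre11A/A, 53bp1-/-, H2ax-/- and Mdc1-/- lines.

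Calls shared with WT had more splits. For the unpaired calls shared by Scid (2), 53bp1-/- (2), H2ax-/- (8) and Mdc1-/- lines (10), 1 of 100 splits, the real one, reached each and the highest other was 0. Such splits also take away the response of each genotype, so they do not test whether 2 genotypes respond alike. Atm-/- and Mre11A/A lines shared 0, a count that every split reaches (all 100, highest others 2 and 0), so the splits tell nothing there. Paired counts were 197 for Scid (highest other 1), 3 for Mre11A/A (highest other 0), 158 for 53bp1-/- (highest other 0), 156 for H2ax-/- (highest other 0) and 290 for Mdc1-/- lines (highest other 1). Each was reached by 1 of 32 swaps, the real one, which is the smallest share possible. All share the WT lines and were not corrected for their number, so chance is not excluded. The Mre11A/A count fell to 0 without Mre11 line 1 or 2. The 3 calls shared with Atm-/- lines were reached by 2 of 32 swaps (highest other 7), so chance cannot be excluded there either. Gene lists called after radiation numbered 31 (1 of 100 splits, highest other 26) and 34 paired (2 of 100, highest other 34). Few splits reached these numbers, but the other splits called a median of 18 lists, and 16 paired. Much of either number can therefore arise from arbitrary splits, and the splits do not tell which lists. For the 9 lists called in untreated lines chance cannot be excluded, since 73 of 100 reassignments of arrays reached that number (highest other 28).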
